A study of Mus musculus with 12 samples.

How the data were processed

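Skin of C3H/HeJ mice was macrodissected, and RNA with an integrity number above 8.0 was made into libraries per the labels, from 250 ng each, with a stranded kit that selects polyadenylated RNA on poly-T beads. Libraries were sequenced on an Illumina HiSeq instrument in paired-end runs of 101 cycles, pooled 5 samples to a pool. The labels do not say which library was in which pool, so no batch could be tested. The authors deposited 1 table of FPKM values, fragment numbers scaled to transcript length and to the mapped fragments of the library, with a column for each of the 12 libraries. Their notes name the mm10 assembly and FastQC 0.11.2, cutadapt 1.7.1, Bowtie2 2.2.3, TopHat2 2.0.13, SAMtools 1.0, Cufflinks 2.2.1 and R 3.1.1; the role of each tool, the gene annotation and any further scaling between libraries are not given in the sources used here. The raw reads were not used here, so the depth behind a value is unknown and no counting error or detection floor is given.

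The table holds 23359 genes. It includes 779 short RNAs, with values up to 2.2e+08 FPKM, and 321 values above 0 but below 1e-06. Among the genes with at least 1 FPKM in at least 3 libraries, 22 were listed at exactly 0 in at least 1 library and stood at 10 FPKM or more in every library where they were not 0. Of these, 18 were short RNAs and the others were Krt1, Krt10, Hrnr and Krtap22-2. They stayed in the fits and counts, but not in the list counts, and no fold is given for them. No pair of libraries was identical.

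Values were analysed as log2(FPKM + 1). The 13761 genes with at least 1 FPKM in at least 3 libraries were tested in limma 3.58.1 under R 4.3.3, in a single fit of all 12 libraries with a mean for each group and an intensity trend in the variance. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method within each of the 5 comparisons, and a gene was called at an adjusted p under 0.05. The fit pools the spread of the 4 groups and so assumes that it is alike, although treated libraries spread more. An exact permutation test of 3 against 3 libraries cannot give a p below 0.10, so none is reported for single genes. On simulated data with 200 genes changed in each comparison, 63% to 66% of 2-fold changes and 88.5% to 90.5% of 4-fold changes were recovered with the right sign, beside 2 to 10 false calls. The simulation gave all groups the same spread and drew genes independently. These figures therefore do not cover the wider spread of the treated libraries or genes that move together.

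Of 41 gene lists of pathways and cell types, 39 had at least 3 tested members. Each was tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with p-values adjusted over the lists. No list call passed with an estimated correlation. The fry test called 12 lists at 6 weeks and 5 at 20 weeks against normal skin, 2 in treated against fibrotic skin and 0 in the other two comparisons. List members were also counted with p-values adjusted over the list alone. The score of a list in a library is the mean log2 value of its members minus the mean over the normal libraries. The lists, comparisons, tests, alternatives and the rule for naming genes were chosen before the data were examined.

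By that rule the text names, for each comparison, up to 3 genes from each list with an adjusted p under 0.05, at least a 2-fold change and no overlap of the groups, taking the lists by their camera p until about 20 genes were named. It adds the 5 highest and 5 lowest fold changes among called genes with a mean of 5 FPKM or more in the higher group and no overlap, without predicted genes and rows of several symbols. Cd36, Thy1, Cav1, Col1a1, Col3a1, Fn1, Cpt1a, Pfkfb3, Mmp2 and Adipoq are named in every comparison. Where fewer than 10 genes were called, the 5 with the smallest p are named. Any other gene is said to have been chosen after its value was seen. The result of a gene that the rule takes at 20 weeks is not reported here, although the counts include it.

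The set of genes that changed at 6 weeks was taken from a fit of the 6 normal and 6-week libraries alone, with an adjusted p under 0.05 and at least a 2-fold change. It was tested with camera and fry in a fit of the 6 treated and fibrotic libraries of 20 weeks alone, so that the choice and the test shared no library. Overlaps between comparisons were set against 50 simulated data sets without group differences and the same shared libraries.

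Alternatives tried were a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, scaling by the median of ratios, rescaling to equal totals after removal of the muscle, hair shaft and cornified lists, a fit of the 6 libraries compared only, a block for the replicate number, each library left out in turn, a 2-fold threshold, and the sets without members of those lists. The totals for the rescaling left out short RNAs and the genes listed at 0. Totals without short RNAs ran from 471486 to 505704 FPKM in normal and from 594926 to 681607 FPKM in 6-week libraries. Leaving out the genes listed at 0, leaving out the short RNAs, and a separate weight for each group were added after seeing the data. Replicate numbers paired libraries only weakly: across genes, the deviations of libraries of the same number correlated at 0.108 to 0.227 between normal skin and 6 weeks and above 0.1 in all 3 pairs for no other comparison, so the unblocked fit was kept; the blocked count there was 5007. Gene positions came from GENCODE M21 for the assembly equivalent to mm10. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.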

Results

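Messenger RNA was sequenced from 12 pieces of skin of C3H/HeJ mice in 4 groups of 3 libraries each: normal skin, fibrotic skin at 6 weeks, fibrotic skin at 20 weeks, and fibrotic skin at 20 weeks that had received CD36highCD90+ fibroblasts (treated skin). CD36 is a fatty acid uptake receptor and CD90, the product of Thy1, is a surface protein of fibroblasts. The title of the series concerns fatty acid oxidation and glycolysis in the upkeep of the skin matrix. The labels do not say how fibrosis was brought about and give no time point for normal skin. They also do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples. The deposited table holds FPKM values, from which the depth of each library cannot be read. Between 12658 and 13364 genes had 1 FPKM or more in a library, and the median FPKM of the tested genes lay between 9.63 and 10.3. Treated libraries spread more than the others: the median SD of a gene on the log2 scale was 0.239 in treated skin, 0.148 in normal skin, 0.142 in fibrotic skin at 6 weeks and 0.148 at 20 weeks (n = 3 each). The tissue composition also differed between libraries, since skeletal muscle fibre genes took from 0.0169% to 2.10% of the FPKM and hair shaft genes from 0.00982% to 2.14%.

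The first comparison, fibrotic skin at 6 weeks against normal skin, asks which transcripts distinguished the early fibrotic tissue. Genes of wound and hyperproliferative keratinocytes rose in 17 of 18 measured members, with a median log2 fold change of 5.85 (adjusted p = 4.54e-09). Krt6b, a keratin of activated epidermis, rose from 2.06 ± 1.05 to 2931 ± 1313 FPKM (SD, n = 3 each). The matrix metalloproteinase gene Mmp12, made mainly by macrophages, rose from 0.516 ± 0.478 to 48.4 ± 4.8 FPKM (SD, n = 3 each), a log2 fold change of 5.07 ± 0.70 (SE, adjusted p = 0.00077). Col1a1, which encodes the main chain of type I collagen, rose from 26.1 ± 9.94 to 114 ± 32.4 FPKM (SD, n = 3 each), a log2 fold change of 2.11 ± 0.44 (SE, adjusted p = 0.00502). Hair follicle stem cell and outer root sheath genes fell in 7 of 13 measured members, with a median log2 fold change of -1.37 (adjusted p = 0.00495). Both lists had an adjusted p = 0.871 with an estimated correlation.

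Among the wound keratinocyte genes, the stefin genes Stfa1 and Stfa2, which encode inhibitors of cysteine proteases, rose by log2 fold changes of 9.81 and 9.20, and the list had 17 members higher when adjusted over the list alone. BC100530, another stefin gene, and Sprr1b, a cornified envelope precursor, were among the 5 highest called genes with log2 fold changes of 10.57 and 8.97. Cornified envelope and late differentiation genes rose in 14 and fell in 3 of 20 members (median log2 fold change 1.26, adjusted p = 0.000282), with 16 higher and 3 lower adjusted over the list alone. That list had an adjusted p = 0.881 with an estimated correlation. Its lower members were the lipoxygenase gene Alox12e (log2 fold change -2.30), the filaggrin family gene Flg2 (-1.58) and Lce1m (-1.02), all parts of the barrier programme, chosen after their values were seen. Cell cycle genes rose in 16 of 28 members (median 0.89, adjusted p = 9.69e-07; adjusted p = 0.881 with an estimated correlation), with 20 higher adjusted over the list alone. They included Ccne1, the cyclin of entry into DNA synthesis (log2 fold change 1.54), the mitotic regulators Birc5 (1.48) and Cdc20 (1.25).

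Macrophage markers rose at 6 weeks in 16 of 20 members (median 1.64, adjusted p = 6.62e-06), with the same count adjusted over the list alone. Matrix degradation genes rose in 15 of 25 (median 0.89, adjusted p = 6.62e-06), with 16 higher and 1 lower adjusted over the list alone. These lists had an adjusted p = 0.871 each with an estimated correlation. Trem2, a receptor of tissue macrophages, rose by a log2 fold change of 2.41 ± 0.25 (SE, n = 3 per group, adjusted p = 0.000209). The endotoxin co-receptor gene Cd14 and the osteopontin gene Spp1 rose by 2.68 and 2.38. The collagenase gene Mmp13 rose by 3.57 and Ctss, which encodes a lysosomal protease of antigen-presenting cells, by 2.77. Cytokine and acute-phase genes rose in 11 of 23 members (median 2.05, adjusted p = 9.5e-05) and neutrophil genes in 5 of 7 (median 2.63, adjusted p = 0.00377), each with an adjusted p = 0.871 with an estimated correlation. The cytokine list also had 11 higher members adjusted over the list alone. Among its members the acute-phase gene Saa3 rose by a log2 fold change of 6.64, Il1b by 4.01 and the neutrophil chemokine gene Cxcl2 by 3.53. The cytokine score of the 6-week replicates 1, 2 and 3 was 2.33, 2.27 and 1.10. The interferon-stimulated list was called (median 1.15, adjusted p = 0.0122; adjusted p = 0.959 with an estimated correlation), although 2 of its 22 members passed over all genes and 0 adjusted over the list alone. Other immune lists were not called, with adjusted p from 0.418 to 0.930. T and NK cell genes had 3 members higher and 4 lower of 17 (median -0.04), B and plasma cell genes 0 called of 3 (median -0.26), dendritic and antigen-presenting cell genes 3 higher of 12 (median 0.08) and mast cell genes 2 higher of 7 (median -0.54, with the test pointing up).

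Collagen and collagen assembly genes rose in 11 and fell in 1 of 26 members at 6 weeks (median 0.81, adjusted p = 0.000282; adjusted p = 0.881 with an estimated correlation), with 13 higher and 1 lower adjusted over the list alone. Col3a1, the type III collagen gene, rose by a log2 fold change of 1.36 ± 0.49 (SE, n = 3 per group, adjusted p = 0.0479). The lower member was Adamts14, a procollagen peptidase gene (-1.503), chosen after its value was seen. Glycolysis genes rose in 12 of 24 members (median 0.86, adjusted p = 9.5e-05; adjusted p = 0.871 with an estimated correlation), with 12 adjusted over the list alone. The glycolytic enzyme genes Pgam1, Eno1 and Pgk1 rose by log2 fold changes of 1.86, 1.75 and 1.53. Pfkfb3, which encodes an enzyme that raises fructose 2,6-bisphosphate and so drives glycolysis, rose by 0.54 ± 0.15 (SE, n = 3 per group, adjusted p = 0.0196). Fatty acid uptake and oxidation genes fell in 15 and rose in 2 of 38 members (median -0.45, adjusted p = 0.00935; adjusted p = 0.898 with an estimated correlation), with 17 lower and 3 higher adjusted over the list alone. The lower members, chosen after their values were seen, included Ppara, a nuclear receptor that turns on fatty acid oxidation (-2.32), Pdk4, which restrains pyruvate oxidation (-2.88), and Acadm, a beta-oxidation dehydrogenase gene (-0.84). The higher ones were Cpt2, of the mitochondrial carnitine shuttle (0.49), and Fabp5, the epidermal fatty acid binding protein gene (4.48), also chosen after their values were seen. Adipocyte markers were not called (2 of 20 lower, median -1.06, adjusted p = 0.0835), but their scores stood at -1.18 to -0.73 in the 6-week libraries against -0.42 to 0.51 in normal ones. Cd36 had a log2 fold change of -1.19 (95% interval -2.45 to 0.06, adjusted p = 0.116). Cpt1a, which encodes the rate-limiting carnitine palmitoyltransferase, had 0.31 (-0.07 to 0.69, adjusted p = 0.173), and neither passed.

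Sebaceous gland genes fell in 9 and rose in 1 of 13 members at 6 weeks (median -1.67, adjusted p = 0.0112; adjusted p = 0.881 with an estimated correlation), with 10 lower and 1 higher adjusted over the list alone. The stearoyl-CoA desaturase gene Scd3 fell by 4.67 on the log2 scale. The higher sebaceous member was the nuclear receptor gene Ppard (1.04), chosen after its value was seen. Caveola genes fell in 3 of 9 members (median -0.80, adjusted p = 0.043; adjusted p = 0.881 with an estimated correlation), among them Cav1, the caveolin gene, with -1.05 ± 0.33 (SE, n = 3 per group, adjusted p = 0.0296). The adipocyte scores stood below normal in the same libraries. Within the follicle list 1 member rose, the morphogen gene Shh (1.17, chosen after its value was seen), and 8 members were lower and 1 higher adjusted over the list alone. Hair shaft genes rose in 20 of 29 members (median 3.33, adjusted p = 3.82e-08; adjusted p = 0.871 with an estimated correlation), with 28 adjusted over the list alone. They included the hair keratin genes Krt85 (4.59) and Krt35 (4.40) and the keratin-associated protein gene Krtap8-1 (4.38). The hair shaft score of the 3 normal libraries itself ranged from -1.70 to 1.58 around their mean, against 2.75 to 3.34 in the fibrotic libraries. The other called lists were targets of p53, with 9 members higher and 1 lower of 19 (median 0.24, adjusted p = 0.0167; adjusted p = 0.871 with an estimated correlation), and cholesterol synthesis. The latter had 6 members higher of 20 (median 0.25, adjusted p = 0.0245; adjusted p = 0.881 with an estimated correlation). With Scd3, the 5 lowest called genes were Serpina3b (-4.94), Ifitm6 (-4.47), Wfdc3 (-4.26) and Hamp2, which was listed at 0 in all 3 fibrotic libraries. The uncalled genes of fixed interest were Thy1 (0.65, adjusted p = 0.098), Fn1, the fibronectin gene (0.73, adjusted p = 0.24), the gelatinase gene Mmp2 (0.82, adjusted p = 0.105) and the adipokine gene Adipoq (-1.36, adjusted p = 0.0829).

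The limma fit called 5409 of the 13761 tested genes at 6 weeks against normal skin, 2427 higher and 2982 lower, and 1578 of them had at least a 2-fold change (867 higher and 711 lower). For 58.1% of all tested genes the groups did not overlap, against 10% by chance. Leaving out replicate 2 of fibrotic skin at 6 weeks brought the count to 3502 and ended 7 of the 32 named calls, those of Krtap8-1, Spp1, Mmp13, Pgk1, Cav1, Col3a1 and Pfkfb3. With any 1 library left out, their adjusted p reached 0.0507 to 0.152. The balance of directions depended on the scaling: after removal of the muscle, hair shaft and cornified lists and rescaling of the rest to equal totals, which moved the median of all genes from -0.05 to -0.39, 1253 genes were higher and 5990 lower. Scaling by the median of ratios gave 2806 higher and 2627 lower genes. The cholesterol and p53 lists had medians of -0.11 and -0.07 under that rescaling, 0.29 and 0.32 above the median of all genes, and the fatty acid list had -0.81, or -0.42 relative to it.

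The second comparison asks which differences from normal skin were present at 20 weeks. Wound keratinocyte genes rose in 13 of 18 members (median 5.45, adjusted p = 6.7e-08), with 14 adjusted over the list alone. Cornified envelope genes rose in 16 and fell in 2 of 20 (median 1.53, adjusted p = 4.82e-06), with 17 and 2 adjusted over the list alone. Glycolysis genes rose in 15 of 24 members (median 1.01, adjusted p = 1.07e-06), with 18 adjusted over the list alone. Hair follicle stem cell and outer root sheath genes fell in 8 of 13 members (median -1.30, adjusted p = 0.000532), with 9 adjusted over the list alone. All 15 lists called at 20 weeks had an adjusted p = 0.885 with an estimated correlation. Rptn, which encodes the cornified envelope protein repetin, rose from 6.37 ± 3.14 to 1206 ± 75.7 FPKM (SD, n = 3 each), a log2 fold change of 7.44 ± 1.15 (SE, adjusted p = 0.00172). Krt15, a keratin of follicle bulge and basal cells, fell from 1839.8 ± 259 to 198 ± 132 FPKM (SD, n = 3 each), a log2 fold change of -3.39 ± 0.54 (SE, adjusted p = 0.00205).

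At 20 weeks Krt6b, Stfa1, Stfa2, Stfa3 and BC100530 rose by log2 fold changes of 9.08, 8.83, 8.53, 8.27 and 10.04, and the late envelope genes Lce3c and Lce1f by 6.28 and 4.18. The cornified members that fell were Flg2 (-0.96) and Lce1m (-1.08), chosen after their values were seen. Eno1 rose from 87.2 ± 24.2 to 341 ± 55.3 FPKM (SD, n = 3 each), a log2 fold change of 1.98 ± 0.34 (SE, adjusted p = 0.00282). Pgam1 and Pfkfb4, which like Pfkfb3 encodes a regulator of glycolytic flux, rose by 1.94 and 1.85, and Pfkfb3 rose by 0.87 ± 0.15 (SE, n = 3 per group, adjusted p = 0.00298). Fatty acid uptake and oxidation genes fell in 11 and rose in 5 of 38 members, with the same counts adjusted over the list alone, and the list was not called (median -0.39, adjusted p = 0.0934). The higher members included Cpt1a (0.51 ± 0.17, SE, n = 3 per group, adjusted p = 0.0426), Cpt2 (0.64), Fabp5 (4.42) and the fatty acid transporter gene Slc27a4 (0.81), all but Cpt1a chosen after their values were seen. Cd36 had a log2 fold change of -0.74 (95% interval -1.99 to 0.51, adjusted p = 0.334). Genes of the citric acid cycle and respiratory chain gave 0 members called of 32 (median 0.01).

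Lhx2, a transcription factor gene of follicle stem cells, fell from 33.98 ± 5.09 to 4.12 ± 0.925 FPKM (SD, n = 3 each), a log2 fold change of -2.78 ± 0.35 (SE, adjusted p = 0.000765). The follicle keratin gene Krt75 fell by 2.68 on the log2 scale. Sebaceous gland genes fell in 6 and rose in 1 of 13 members at 20 weeks (median -1.71, adjusted p = 0.0314), with 7 and 1 adjusted over the list alone. The higher one was Ppard (1.28, chosen after its value was seen). Caveola genes fell in 3 of 9 (median -0.59, adjusted p = 0.036), and Cav1 itself had -0.88 (adjusted p = 0.0634). Adipocyte markers had 1 member higher and 1 lower of 20 and were not called (median -0.99, adjusted p = 0.0679), with scores of -1.26 to -0.64 against -0.42 to 0.51 in normal skin. Scd3, Serpina3b, Ifitm6, Hamp2 and Serpina3j were the 5 lowest called genes, with log2 fold changes from -4.99 to -4.25. The hair shaft list, which was called at 6 weeks, had 2 members higher of 29 and was not called (median 0.74, adjusted p = 0.0606). The adjusted p with an estimated correlation was 0.885 for each of the called lists here as well.

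Matrix degradation genes rose in 14 and fell in 2 of 25 members at 20 weeks (median 0.70, adjusted p = 0.0016; adjusted p = 0.885 with an estimated correlation), with 16 and 2 adjusted over the list alone. Mmp12, Mmp13 and Ctss rose by log2 fold changes of 4.21, 3.42 and 1.83. The lower members, chosen after their values were seen, were the aggrecanase gene Adamts5 (-0.95) and the fibroblast activation protein gene Fap (-0.99). Macrophage markers rose in 8 and fell in 1 of 20 (median 0.97, adjusted p = 0.00449), and collagen genes rose in 6 and fell in 1 of 26 (median 0.34, adjusted p = 0.036). Both lists had an adjusted p = 0.885 with an estimated correlation, and counts of 8 and 1 and of 5 and 1 adjusted over the list alone. The collagen score was 0.37, 0.84 and -0.05 in replicates 1, 2 and 3 of 20 weeks, against -0.24 to 0.28 in normal skin. Replicate 3 thus lay within the normal range for the list as a whole. Dermal fibroblast markers had 6 members lower and 0 higher of 18, with 8 lower adjusted over the list alone, and were not called (median -0.47, adjusted p = 0.0679). Their scores were -1.02 to -0.32 against -0.20 to 0.30 in normal skin. The lower members of the macrophage and collagen lists were the scavenger receptor gene Cd163 (-1.01) and Adamts14 (-1.87), chosen after their values were seen. Col1a1 rose to 99.95 ± 45.7 FPKM (SD, n = 3), a log2 fold change of 1.86 ± 0.44 (SE, adjusted p = 0.0104). Col3a1 had 0.39 (95% interval -0.69 to 1.47), Fn1 had -0.08 and Mmp2 had 0.18, none of which passed. Cholesterol synthesis genes rose in 10 of 20 members (median 0.41, adjusted p = 0.00119), among them Sqle, the squalene epoxidase gene (1.17), Hsd17b7 (1.07) and Mvd (1.02). Smaller counts of higher members were found for p53 targets (8 of 19, median 0.30), cytokines (4 of 23, median 1.07), neutrophil genes (3 of 7, median 1.69), interferon-stimulated genes (2 of 22, median 1.29) and cell cycle genes (1 of 28, median 0.34). Their adjusted p ran from 0.00202 to 0.036 and was 0.885 with an estimated correlation. The interferon-stimulated members included the antiviral gene Oas1a (2.26). Thy1 (0.28, adjusted p = 0.484) and Adipoq (-1.38, adjusted p = 0.0866) did not pass.

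At 20 weeks against normal skin 4605 genes were called, 2102 higher and 2503 lower, and 1311 had at least a 2-fold change (730 higher and 581 lower). The groups did not overlap for 54.6% of all tested genes, against 10% by chance. Without replicate 1 of fibrotic skin at 20 weeks the count was 3028, and 7 of the 30 named calls ended, among them those of Sqle, Mmp13, Ctss, Oas1a, Serpina3b and Cpt1a. With any 1 library left out, the adjusted p of these genes reached 0.0565 to 0.148. Under the rescaling described for 6 weeks the median of all genes moved from -0.04 to -0.34, and 1094 genes were higher and 5399 lower, whereas the median of ratios gave 2406 higher and 2237 lower. The p53, collagen, cell cycle and cholesterol lists then had medians of -0.02, 0.03, 0.05 and 0.09, which were 0.32, 0.37, 0.39 and 0.43 above that of all genes, and the caveola list had -0.92, or -0.58 relative to it. The changes at 6 and 20 weeks, both taken against the same 3 normal libraries, correlated across 13739 genes with r = 0.871, against 0.501 in simulated data without group differences that shared the normal libraries. Genes called higher at both times numbered 1403 and genes called lower at both 1980, and 2 genes were called in opposite directions. Opposite signs were found for 17.3% of genes, against 33.4% in the simulated data. Both comparisons used the same 3 normal libraries, which could not be divided between them, and genes are not independent replicates.

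**Figure D1:**
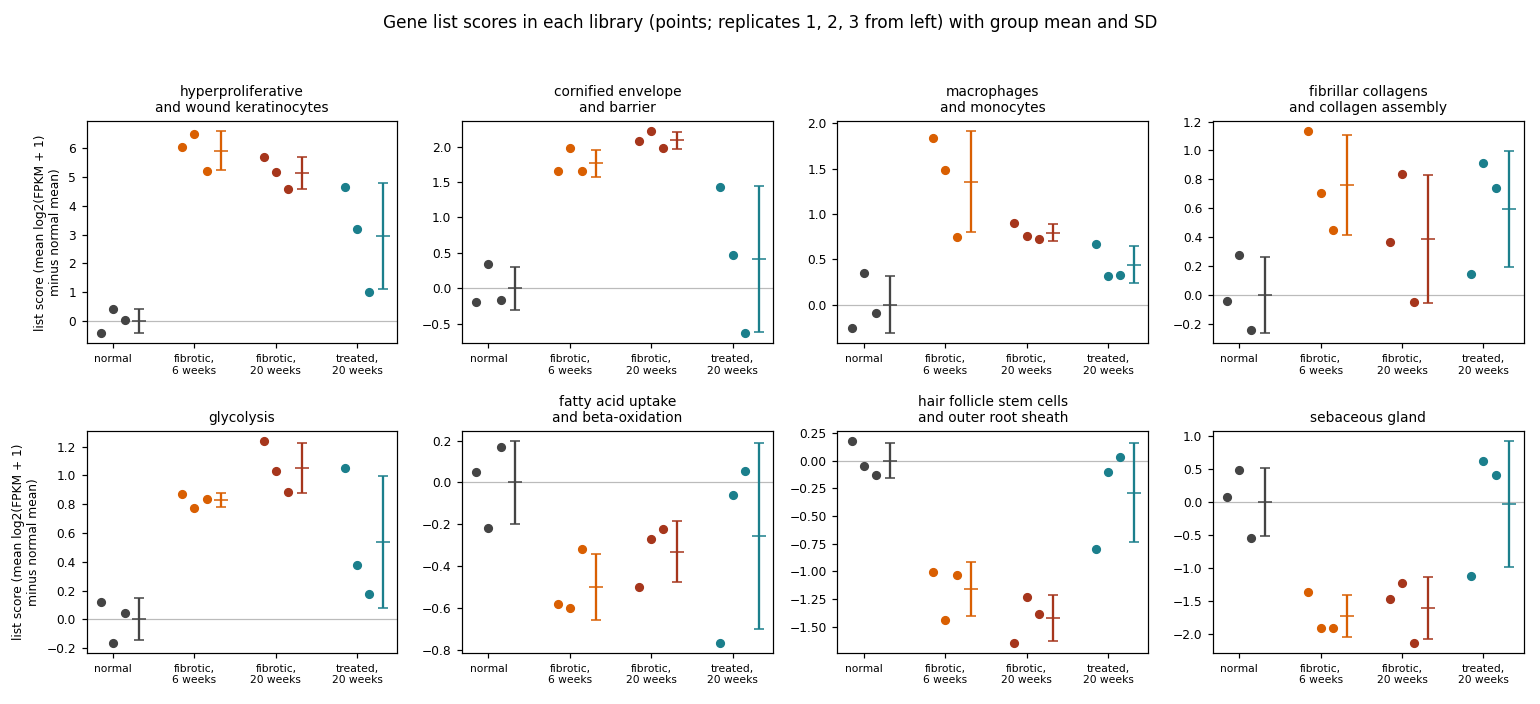
Scores of 8 fixed gene lists, given as the mean log2(FPKM + 1) of the members minus the mean of normal skin, for each of the 12 libraries (points) with the mean and SD of each group beside them. The wound keratinocyte score had a mean of 5.93 at 6 weeks and 5.14 at 20 weeks, and the 3 treated libraries stood at 4.66, 3.19 and 1.02.

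The third comparison, fibrotic skin at 20 weeks against 6 weeks, asks how the fibrotic tissue differed over time. The called genes were few and named by the 5 smallest p-values. Coch, which encodes the secreted protein cochlin, fell from 16.6 ± 3.8 to 1.77 ± 0.542 FPKM (SD, n = 3 each), a log2 fold change of -2.66 ± 0.18 (SE, adjusted p = 0.000232). Olfm1, the olfactomedin 1 gene, fell to 7.53 ± 0.681 FPKM (SD, n = 3), a log2 fold change of -1.28 ± 0.17 (SE, adjusted p = 0.0419). Amd1, an enzyme gene of polyamine synthesis, rose by a log2 fold change of 5.31 ± 0.52 (SE, n = 3 per group, adjusted p = 0.00348). Its near-identical relative Amd2 stood at 73.7 ± 2.65 FPKM at 6 weeks and 28.1 ± 13.6 at 20 weeks, and the sum of both genes stood at 73.7 ± 2.66 and 73.4 ± 11.5 FPKM (SD, n = 3 each). The total thus showed no rise, and the Amd1 call cannot be told from reads assigned to one gene or the other. The keratinocyte genes Krt1 and Hrnr were also called, but both were listed at exactly 0 in all 3 libraries of 20 weeks, where Krt1 stood at 14514 ± 2047 FPKM at 6 weeks (SD, n = 3), so no fold is given. Krt10, the partner keratin of Krt1, was likewise listed at 0 in replicates 2 and 3 of 20 weeks and at 16040 FPKM in replicate 1.

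Apart from Krt1 and Hrnr, which were left out of the list counts because they were listed at 0, no member of a fixed list passed over all genes between the time points. By camera 13 lists were called, and all 13 had an adjusted p = 0.789 with an estimated correlation. Hair shaft genes had a median log2 fold change of -2.45 (adjusted p = 1.87e-10), cell cycle genes -0.47 (adjusted p = 3.43e-06), macrophage markers -0.49 (adjusted p = 0.0007) and fibroblast markers -0.59 (adjusted p = 0.00111). Adjusted over the list alone, 2 hair shaft genes, 1 macrophage gene and 1 fibroblast gene were lower, and 0 cell cycle genes. Skeletal muscle genes had a median of 1.28 (adjusted p = 0.0382), with 0 members passing, while their score had an SD of 2.09 at 6 weeks and 0.99 at 20 weeks (n = 3 each). Among the genes of fixed interest, Col1a1 had a log2 fold change of -0.25, Col3a1 -0.97, Fn1 -0.81, Mmp2 -0.64, Thy1 -0.37, Cav1 0.17, Cd36 0.45, Cpt1a 0.20, Pfkfb3 0.33 and Adipoq -0.02, with adjusted p from 0.259 to 0.987.

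Fibrotic skin at 20 and 6 weeks differed in 5 called genes, 1 higher and 4 lower, with 2737 genes at an unadjusted limma p under 0.05 in this contrast and 30.9% without overlap, against 10% by chance. The count was 109 without replicate 3 of 6 weeks and 12 without replicate 1 of 20 weeks. It was 550, 10 and 15 without treated replicates 1, 2 and 3, which add to the pooled spread alone, and 478 (287 higher and 191 lower) with only the 6 libraries compared. Without normal replicate 1, replicate 1 or 2 of 6 weeks or any replicate of 20 weeks the call of Olfm1 ended, with an adjusted p up to 0.211, while those of Coch and Amd1 held. It was 23 (16 higher and 7 lower) among genes with a mean of 5 FPKM or more and 2 with the rows listed at 0 left out, and rescaling gave 3 higher and 3 lower genes.

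The fourth comparison, treated against fibrotic skin at 20 weeks, asks what the transplanted fibroblasts left different in the tissue. Cornified envelope genes fell in 15 of 20 members (median -1.59, adjusted p = 8.63e-08), and the follicle stem cell and outer root sheath genes rose in 8 of 13 (median 1.08, adjusted p = 8.45e-06). These lists had an adjusted p = 0.775 and an adjusted p = 0.689 with an estimated correlation. Rptn fell from 1206 ± 75.7 to 142 ± 163 FPKM (SD, n = 3 each), a log2 fold change of -4.44 ± 1.15 (SE, adjusted p = 0.0315). Lhx2 rose from 4.12 ± 0.925 to 21.8 ± 9.98 FPKM (SD, n = 3 each), a log2 fold change of 2.05 ± 0.35 (SE, adjusted p = 0.0152). The Wnt effector gene Lef1 rose by 1.78 ± 0.27 (SE, n = 3 per group, adjusted p = 0.0151). The treated libraries differed widely from one another: in replicates 1, 2 and 3 Rptn stood at 323, 98.9 and 4.35 FPKM and Lhx2 at 10.3, 26.3 and 28.7. These calls rest on a spread pooled over all 12 libraries, and 3 genes were called when only the 6 libraries compared were fitted.

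Of the epidermal genes, the late envelope gene Lce3c and Casp14, which encodes a protease of terminal keratinocyte differentiation, fell by 3.69 and 2.76 on the log2 scale in treated skin, and 18 cornified members were lower adjusted over the list alone. Wound keratinocyte genes fell in 3 of 18 members (median -2.62, adjusted p = 0.0025; adjusted p = 0.775 with an estimated correlation), with 9 adjusted over the list alone. They were the interleukin genes Il1f6 (-3.11) and Il1f8 (-2.61) and Serpinb3a (-2.90). The 5 lowest called genes were Rptn, Spink7 (-4.06), Lce3e (-3.92), Lce3d (-3.72) and Lce3b (-3.69). Glycolysis genes had a median of -0.56 (adjusted p = 0.00507; adjusted p = 0.782 with an estimated correlation), with 1 of 24 members lower and 0 adjusted over the list alone. That member was Pdk1, which restrains pyruvate oxidation (-0.42, chosen after its value was seen). Eno1 stood at 352, 165 and 121 FPKM in treated replicates 1, 2 and 3. The wound keratinocyte score of these replicates was 4.66, 3.19 and 1.02, against 4.57 to 5.69 in fibrotic skin at 20 weeks. The glycolysis score was 1.05, 0.38 and 0.18 against 0.89 to 1.24. For both lists the score of replicate 1 thus lay within the fibrotic range.

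Wnt and hedgehog pathway genes rose in 7 and fell in 1 of 21 members (median 0.86, adjusted p = 6.15e-05; adjusted p = 0.689 with an estimated correlation), with 12 and 1 adjusted over the list alone. They included the Wnt feedback genes Nkd2 (1.25) and Notum (1.20), and the lower member was the ligand gene Wnt4 (-0.51, chosen after its value was seen). In the follicle list Krt75 rose by 2.64 and Shh by 1.12, and 11 members were higher adjusted over the list alone. The rotation test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called these 2 lists, with adjusted p of 0.0111 for the pathway list and 0.0164 for the follicle list. Both lists contain Gli1 and Shh, and Lef1 belongs to the pathway and hair shaft lists, so these lists are not separate evidence. Hair shaft genes rose in 6 of 29 members (median 2.70, adjusted p = 8.63e-08; adjusted p = 0.775 with an estimated correlation), with 18 adjusted over the list alone. Among them were Krt83 (3.25), Krt33b (3.07) and Krt35 (2.90). The hair shaft score of treated replicates 1, 2 and 3 was 3.50, 1.44 and 4.71. Krtap19-4 and Krtap19-1, which encode hair keratin-associated proteins, and Serpina3j were among the 5 highest called genes, with 4.18, 4.01 and 4.17.

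Sebaceous gland genes rose in treated against fibrotic skin in 6 of 13 members (median 1.73, adjusted p = 0.00166; adjusted p = 0.775 with an estimated correlation), with 10 higher and 1 lower adjusted over the list alone. Among them were Scd3 (3.76), the fatty acid elongase gene Elovl3 (2.66) and the wax synthase gene Awat1 (2.34). Adipocyte genes rose in 2 and fell in 1 of 20 members (median 1.43, adjusted p = 6.98e-05; adjusted p = 0.775 with an estimated correlation), with 12 and 1 adjusted over the list alone. The higher ones were the adipokine genes Lep (2.27) and Retn (2.08), and the lower one was Cebpa, a transcription factor gene of fat cells (-0.53, chosen after its value was seen). Fatty acid and triglyceride synthesis genes rose in 4 of 20 (median 0.92, adjusted p = 0.0156; adjusted p = 0.785 with an estimated correlation), with 5 and 1 adjusted over the list alone. Cholesterol synthesis genes had 1 member higher and 2 lower of 20 and were not called (median -0.16, adjusted p = 0.244). Adipoq had 1.52 (adjusted p = 0.0946) and stood at 50.2, 120 and 261 FPKM in treated replicates 1, 2 and 3. Scd3 stood at 1.95, 72.5 and 97.7 FPKM. Skeletal muscle genes, the other tissue below the dermis, had scores of -3.29, -0.08 and 0.67 in the same libraries. Fibroblast markers rose in 3 of 18 members (median 0.58, adjusted p = 0.0101; adjusted p = 0.775 with an estimated correlation), namely Cd34 (1.08), Fap (0.76) and Pi16 (1.73), chosen after their values were seen, with 4 adjusted over the list alone. Smooth muscle (median 0.84), melanocyte (0.66) and blood endothelium (0.54) lists were called with 0, 1 and 0 members higher, adjusted p from 0.0313 to 0.0315, and an adjusted p from 0.775 to 0.88 with an estimated correlation. In treated replicates 1, 2 and 3 the smooth muscle score was -0.70, 0.81 and 1.20, against -0.55 to 0.13 in fibrotic skin at 20 weeks. The endothelium score was -0.69, 0.66 and 1.07 against -0.37 to 0.17, and the melanocyte score -0.70, -0.19 and 0.25 against -0.89 to -0.81. The adipocyte score was -0.77, 0.57 and 1.56 against -1.26 to -0.64, and the fibroblast score -0.34, 0.06 and 0.06 against -1.02 to -0.32. For smooth muscle, endothelium, adipocytes and fibroblast markers the rise was thus absent in replicate 1, which did not lie above the fibrotic range.

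Collagen genes were not called in treated against fibrotic skin (median 0.24, adjusted p = 0.189), and 1 of 26 members fell, Col12a1, a fibril-associated collagen gene (-1.09, chosen after its value was seen). Col1a1 stood at 104 ± 49.5 FPKM in treated skin (SD, n = 3), a log2 difference of 0.02 (95% interval -0.953 to 1.002). It stood at 51.2, 149 and 112 FPKM in treated replicates 1, 2 and 3. Col3a1 had 0.13 (95% interval -0.95 to 1.21), Fn1 0.22, Mmp2 0.04, Thy1 0.50 and Cav1 0.63, none of which passed. Matrix degradation genes (median -0.27, adjusted p = 0.474) had 2 members higher, Adamts5 (1.12) and Fap (0.76), and 1 lower, the lysosomal protease gene Ctsd (-0.75), chosen after their values were seen. Fatty acid uptake and oxidation genes were not called (median 0.07, adjusted p = 0.572), with 3 of 38 members lower, Cpt1a, Cpt2 (-0.44) and Fabp5 (-1.93), the latter pair chosen after their values were seen. Cpt1a fell from 45.8 ± 5.00 to 28.2 ± 2.45 FPKM (SD, n = 3 each), a log2 fold change of -0.68 ± 0.17 (SE, adjusted p = 0.029). Cd36 had 0.74 (95% interval -0.51 to 2.00, adjusted p = 0.374) and stood at 22.4, 85.9 and 131 FPKM in replicates 1, 2 and 3. Pfkfb3 had 0.03 (95% interval -0.31 to 0.37).

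**Figure D2:**
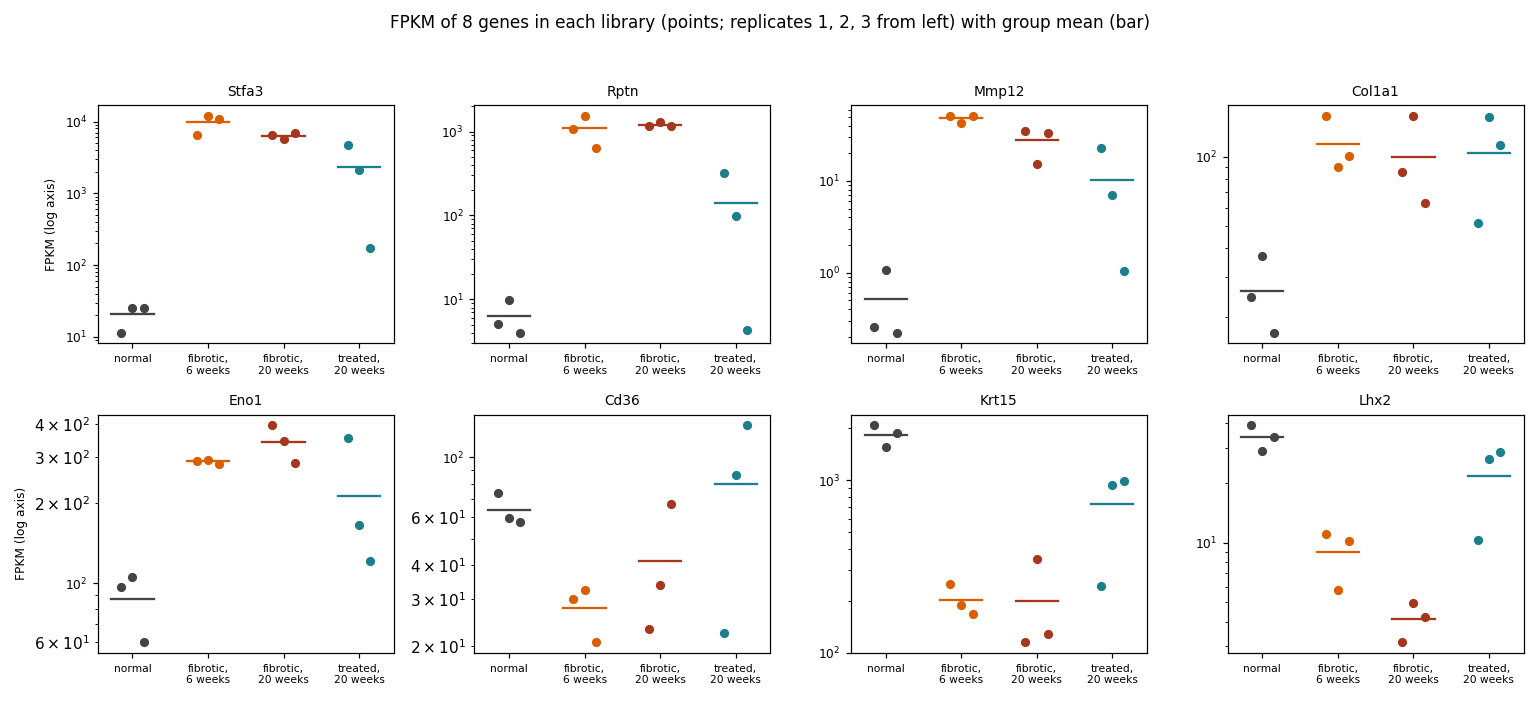
FPKM on a log axis of Stfa3, Rptn, Mmp12, Col1a1, Eno1, Cd36, Krt15 and Lhx2 in the 4 groups, with a point for each library and a bar at the mean of each group of 3. The treated libraries spread widely for Rptn, from 4.35 to 323 FPKM, while the mean of Col1a1 was 99.95 FPKM in fibrotic skin at 20 weeks and 104 FPKM in treated skin.

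In treated against fibrotic skin at 20 weeks 2108 genes were called, 612 higher and 1496 lower, and 541 had at least a 2-fold change (163 higher and 378 lower). The groups did not overlap for 32.2% of tested genes, against 10% by chance. Under the rescaling, which moved the median of all genes from -0.00 to 0.26, 2333 genes were higher and 686 lower. The glycolysis, fibroblast, melanocyte and endothelium lists then had medians of -0.28, 0.90, 0.998 and 0.84, or -0.54, 0.64, 0.74 and 0.58 relative to that of all genes. The count was 341, 959 and 3 without fibrotic replicates 1, 2 and 3 of 20 weeks, and 5216, 532 and 297 without treated replicates 1, 2 and 3. With only the 6 libraries fitted, 3 genes were called, of which the cytochrome P450 gene Cyp2s1 (-1.62, chosen after its value was seen) was the one not affected by values listed at 0. In that fit 0 of the 28 named calls passed, with a lowest adjusted p of 0.128. That fit called 3985 genes (1853 higher and 2132 lower) without treated replicate 1, and 2 to 5 without any other single library. All 28 named calls were lost without fibrotic replicate 3 of 20 weeks. A fit with a separate weight for each group, chosen after seeing the data, gave 1204 genes, and the replicate-blocked fit gave 1365.

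The genes changed at 6 weeks were then followed into the treated tissue in libraries that had no part in choosing them. Of 921 genes that rose at least 2-fold at 6 weeks, 700 (76.0%) were lower in treated than in fibrotic skin at 20 weeks, against 50.6% of all genes, with a median log2 difference of -0.53. Of 761 genes that fell, 651 were higher, with a median of 0.50. The camera p was 2.26e-10 for the genes that rose and 2.63e-16 for those that fell, whereas the p with an estimated correlation was 0.318 and 0.232. The fry p was 0.118 and 0.116, and its test for change in either direction gave 0.00981 and 0.0514. Relative to the mean of normal skin, the median log2 difference of the genes that rose was 1.34, 0.63 and 0.34 in treated replicates 1, 2 and 3, and 1.44, 1.26 and 1.16 in the fibrotic libraries of 20 weeks. For the genes that fell it was -1.17, -0.53 and -0.51, against -1.36, -1.05 and -1.14. The normal libraries had a part in choosing these genes, so the distances from normal skin may be overstated. The treated-against-fibrotic differences do not share that limit. The median for the genes that rose stayed between -0.79 and -0.31 with any 1 library left out, and that for the genes that fell between 0.36 and 0.74.

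The fifth comparison, treated against normal skin, asks how the treated tissue differed from normal skin. Hair shaft genes rose in 19 of 29 members (median 3.73, adjusted p = 5.46e-13), with 28 adjusted over the list alone. Their score was 3.50, 1.44 and 4.71 in treated replicates 1, 2 and 3, so replicate 2 lay within the normal range of -1.70 to 1.58. In fibrotic skin at 20 weeks the score was 0.51 to 1.32 and this list was not called. Wound keratinocyte genes rose in 7 of 18 (median 2.65, adjusted p = 2.45e-06), with 10 adjusted over the list alone. Stfa3 rose from 20.8 ± 8.09 to 2355 ± 2302 FPKM (SD, n = 3 each), a log2 fold change of 5.88 ± 0.95 (SE, adjusted p = 0.00481). It stood at 4762, 2128 and 176 FPKM in treated replicates 1, 2 and 3. Col1a1 rose by a log2 fold change of 1.89 ± 0.44 (SE, n = 3 per group, adjusted p = 0.0175), and Pfkfb3 by 0.90 ± 0.15 (SE, n = 3 per group, adjusted p = 0.00571). All 12 lists called were higher, and each had an adjusted p = 0.961 with an estimated correlation.

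Collagen genes rose in 4 of 26 members in treated against normal skin (median 0.66, adjusted p = 7.57e-05), with 2 adjusted over the list alone, and Col6a2, a type VI collagen gene, rose by 1.35. The collagen score was 0.15, 0.91 and 0.74 in treated replicates 1, 2 and 3, against -0.24 to 0.28 in normal skin. Matrix glycoprotein genes rose in 5 of 28 (median 0.45, adjusted p = 0.0133), among them tenascin C (Tnc, 2.02) and biglycan (Bgn, 1.30). Matrix degradation genes rose in 4 of 25 (median 0.31, adjusted p = 0.000631), among them Adamts1 (1.07). Glycolysis genes rose in 4 of 24 (median 0.60, adjusted p = 0.000398), with 7 higher and 1 lower adjusted over the list alone. Eno1, Pkm and Pfkl rose by 1.17, 1.01 and 1.004. Cell cycle genes rose in 6 of 28 (median 0.37, adjusted p = 7.57e-05), with the replication gene Mcm5 at 1.10 and Ccne1 at 1.08. Macrophage markers rose in 5 of 20 (median 0.55, adjusted p = 0.0179), with Trem2 and the complement gene C1qa at 1.27 each and C1qc at 1.23. Cholesterol synthesis (5 of 20, median 0.24), Wnt and hedgehog genes (5 of 21, median 0.24), cytokines (2 of 23, median 0.67) and interferon-stimulated genes (0 of 22, median 0.95) made up the remaining calls. Their adjusted p ran from 0.000398 to 0.0309, and the adjusted p with an estimated correlation was 0.961 for every one of these lists. The T cell chemokine gene Ccl5 rose by 2.46 and Ifng by 1.41. In treated replicates 1, 2 and 3 the interferon-stimulated score was 2.73, 0.26 and 0.11, against -0.22 to 0.41 in normal skin, the cytokine score was 2.12, 0.44 and 0.25, and Ccl5 stood at 52.1, 5.62 and 6.26 FPKM.

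The hair shaft examples in treated against normal skin were Krt35 (4.50), Krt83 (4.31) and Krt73 (4.29), and the keratinocyte ones BC100530 (6.65), Stfa1 (5.52), Stfa2 (5.08) and Sprr1b (4.76). Mvd rose by 1.18. The lowest called genes were Ifitm6 (-3.05), Hamp2 (-2.89), Mrgprb3 (-2.74), the interleukin 22 decoy receptor gene Il22ra2 (-2.68) and the secretoglobin gene Scgb1a1 (-2.38). Among the lists not called here, follicle stem cell genes had a median of -0.38 (adjusted p = 0.524), with 2 members lower, Cd34 (-0.99) and Nfatc1 (-0.68), and 1 higher, Shh (1.499), all chosen after their values were seen. Sebaceous genes had a median of -0.04 (adjusted p = 0.656), fatty acid uptake and oxidation genes -0.34 (adjusted p = 0.165), caveola genes -0.32 (adjusted p = 0.513) and cornified genes 0.23 (adjusted p = 0.247). Cd36 had 0.00 (95% interval -1.25 to 1.26), Cpt1a -0.17, Col3a1 0.52, Fn1 0.14, Mmp2 0.22, Thy1 0.78, Cav1 -0.25 and Adipoq 0.13, none of which passed.

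In treated against normal skin 2855 genes were called, 1042 higher and 1813 lower, and 509 had at least a 2-fold change (309 higher and 200 lower). The groups did not overlap for 37.5% of tested genes, against 10% by chance, and scaling by the median of ratios gave 1263 higher and 1352 lower genes. The count was 1796 and 904 without normal replicates 2 and 3, and without replicate 3 the calls of 19 of the 30 named genes ended, Col1a1, Eno1 and Tnc among them, against 12 without replicate 1. It was 138 (33 higher and 105 lower) with only the 6 libraries fitted, where Trem2 and Mrgprb3 were the 2 named calls that passed, and 1311 with a separate weight for each group. The changes at 20 weeks against normal skin and the treated-against-fibrotic changes correlated negatively across genes, with r = -0.655, but the shared fibrotic libraries alone gave -0.497 in simulated data. Genes higher in fibrotic than in normal skin and lower after treatment numbered 839, and those lower and then higher 347. Independent calls would give 229 and 111, figures that do not allow for the shared fibrotic libraries. Called in the same direction in both comparisons were 5 higher and 25 lower genes. All these calls rest on the pooled spread, and the fit of the treated and fibrotic libraries of 20 weeks alone called 3 genes. Opposite signs were found for 70.0% of genes, against 66.7% in the simulated data.

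The genes of fixed interest lie in the mm10 assembly as follows. Col1a1 spans 94936224 to 94953042 on chromosome 11, Col3a1 45311538 to 45349706 and Fn1 71585520 to 71653200 on chromosome 1, and Mmp2 92827291 to 92853420 on chromosome 8. Cd36 spans 17781690 to 17888801 on chromosome 5, Cpt1a 3322334 to 3385733 on chromosome 19, Pfkfb3 11471433 to 11554077 on chromosome 2 and Adipoq 23146536 to 23158028 on chromosome 16. Cav1 spans 17306335 to 17341452 on chromosome 6 and Thy1 44043384 to 44048579 on chromosome 9. Of the other genes described in full, Mmp12 spans 7344381 to 7369499 on chromosome 9, Eno1 150236721 to 150248879 on chromosome 4, Rptn 93393699 to 93399442 on chromosome 3, Krt15 100131758 to 100135928 on chromosome 11 and Lhx2 38339281 to 38369733 on chromosome 2. Stfa3 spans 36450537 to 36455392 on chromosome 16, Trem2 48346401 to 48354147 on chromosome 17, Lef1 131110471 to 131224356 on chromosome 3, Coch 51593341 to 51605771 on chromosome 12, Amd1 40287458 to 40302186 on chromosome 10 and Olfm1 28192992 to 28230736 on chromosome 2.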

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

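All tests of an explanation in this part were chosen only after the result was seen, except the scaling test of the wound keratinocyte genes and the counts of other splits. The effects against normal skin at 6 and at 20 weeks differed, by the test of 20 against 6 weeks itself, for 3 genes and 13 lists. The genes were Amd1 with a log2 difference of 5.31, Coch with -2.66 and Olfm1 with -1.28. The lists, by their median log2 difference, were hair shaft (-2.45), cytokines (-0.60), fibroblast markers (-0.59), melanocytes (-0.56), macrophages (-0.49), matrix degradation (-0.47), cell cycle (-0.47), Wnt and hedgehog (-0.37), collagens (-0.34), protease inhibitors (-0.29), basal and spinous keratinocytes (0.21), T and NK cells (0.43) and skeletal muscle (1.28). All 13 lists had an adjusted p = 0.789 with an estimated correlation. The sum of Amd1 and its relative Amd2 was 73.7 FPKM at 6 weeks and 73.4 at 20 weeks. The Amd1 difference is therefore not a change of that total and may reflect how reads were assigned between both genes.

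Wound keratinocyte genes were higher in fibrotic skin at 20 weeks than in normal skin. More epidermis in the dissected piece would raise basal keratinocyte genes alike, but the wound score rose above the basal score by 4.56 (2 standard errors, 3.92 to 5.20). Reads moved between paralogs would leave family totals alike, but the lowest log2 ratio of a family total was 3.29, for the Sprr family, and scaling by the median of ratios left the list median at 5.48. These values argue against the 3 technical explanations as the whole cause. A change of epidermal state that accompanies fibrosis remains as a hypothesis, since normal skin has no time point and the pattern was found in the same data.

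The treated libraries spread between the levels of fibrotic and normal skin. A swap with a fibrotic library of 20 weeks could leave one of these as low as treated replicate 2. Their lowest median of the genes that rose at 6 weeks was 1.16 (0.877 after 2 SD), above the 0.629 of treated replicate 2. The SD came from the same 3 libraries, and treated replicate 1, at 1.34, lay among their values of 1.16 to 1.44. A treated library of that kind under a fibrotic label would not stand out, so the test cannot decide on such a swap. Muscle content stays open as a cause of the spread. Within the other groups the median of the genes that rose at 6 weeks changed with the muscle score by -0.06 per unit where -0.24 was needed (exact permutation p = 0.00926, and 0.0185 for a slope of 0). Those genes were chosen in the normal and 6-week libraries, which also entered that test. A choice for small spread within groups pushes the slope towards 0, so the test cannot decide. In fibrotic replicates 1, 2 and 3 of 20 weeks, outside the choice, the median was 1.44, 1.26 and 1.16 at muscle scores of -0.94, 0.20 and 1.03. A wrong label of treated replicate 1 stays open: its mean r across genes was 0.932 with the fibrotic libraries of 20 weeks, which correlated with one another at 0.944 to 0.966, and 0.897 with the other treated ones, and its r with those of 6 weeks was 0.933 to 0.944. Against a label taken from 20 weeks, its Lef1 (9.59 FPKM), Coch (7.71 FPKM) and hair shaft score (3.50) stood above those libraries (1.36 to 2.23, 1.35 to 2.38 and 0.51 to 1.32). Krt1, listed at 0 in them, stood at 7509 FPKM, and Amd1 at 27.4 FPKM against 0.0137 to 0.0286 at 6 weeks. Krt1 and Amd1 may reflect how reads were assigned rather than the tissue. The sum of Amd1 and Amd2 was 73.7 FPKM at 6 weeks and 73.4 at 20 weeks. All these are values of a single library picked after they were seen. An uneven effect of the transplanted cells is a biological candidate explanation that the labels give no measure to test.

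Hair follicle stem cell and outer root sheath genes were lower in fibrotic skin at 20 weeks than in normal skin. The hair cycle stage would need the stem cell score to change by -1.64 per unit of the hair shaft score, and within groups it changed by -0.03 (exact permutation p = 0.00154 for the needed slope). The needed slope is poorly known, because the hair shaft scores at 20 weeks (0.51 to 1.32) lay within the normal range (-1.70 to 1.58). The p treats that slope as known, so the test cannot decide on the hair cycle stage. Dilution by other cells would lower endothelial genes alike, but the follicle score fell below the endothelial score by -1.25 (-1.66 to -0.84). The size of that difference depends on the reference, which was picked after the result was seen. The mean score at 20 weeks was -1.42 for the follicle list and -0.17 for endothelium. It was -1.61 for sebaceous gland, -0.90 for adipocytes, -0.86 for melanocytes and -0.61 for fibroblast markers, while basal keratinocytes (0.59) and macrophages (0.79) rose. A loss of follicle stem and sheath cells in fibrotic skin is consistent with these values but was not tested apart from lower expression in the same cells.

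The 6 libraries of a comparison can be split in 10 ways into 3 and 3, too few for a share under 0.05. At 6 weeks against normal skin the real split called 5409 genes and the highest other 1, and at 20 weeks against normal skin the real split called 4605 and the highest other 0. For 20 against 6 weeks it was 5 and 0, for treated against fibrotic skin 2108 and 1, and for treated against normal skin 2855 and 3, so in each of these 1 split, the real one, reached its count. Every split was fitted with all 12 libraries. A split that mixes the groups puts their difference into the spread, so few calls there follow once the groups differ at all. These counts therefore add no support beyond the fit itself. For the genes that rose at 6 weeks, 3 of 10 splits of the treated and fibrotic libraries gave a median at least as large as the real 0.53 in size, with a highest other of 0.60, and for the genes that fell 2 of 10 did, with 0.50 and 0.57.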

How the results depend on the processing

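Of the 5 counts of called genes, those of 6 and 20 weeks against normal skin stayed within 1.5 times of 5409 and 4605 under every alternative except the 2-fold threshold and single libraries left out, while those involving treated skin and that of 20 against 6 weeks did not. The deposited FPKM values give no depth, so what depth limits is unknown, and 3 libraries per group limit each count. With only the 6 libraries compared, 478 genes were called for 20 against 6 weeks (287 higher), 3 for treated against fibrotic skin and 138 for treated against normal skin. The fit for treated against fibrotic skin called 3985 genes without treated replicate 1. A weight for each group, chosen after seeing the data, gave 859, 1204 and 1311 for these comparisons (62.7% higher for 20 against 6 weeks), with a weight of 0.473 for treated skin. The replicate block gave 1365 for treated against fibrotic skin. A mean of 5 FPKM gave 23 for 20 against 6 weeks and leaving out the genes listed at 0, added after seeing the data, gave 2, since Krt1 and Hrnr were removed and Olfm1 was no longer called. The 2-fold threshold gave 1578, 1311, 541 and 509 where the main counts were 5409, 4605, 2108 and 2855, by its construction. Leaving out the short RNAs, no filter, the pseudocount and the scalings left each count within 1.5 times. The sets that rose and fell at 6 weeks stayed on their side under the pseudocount, the mean of 5 FPKM, the scalings, the replicate block and without muscle, hair shaft and cornified members. The scalings moved the balance of higher and lower genes within the counts.

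With an estimated correlation 0 lists were called in each of the 5 comparisons, against 17, 15, 13, 13 and 12, and the sets that rose and fell at 6 weeks had medians of -0.53 and 0.50 with p of 0.318 and 0.232; the genes of a list move together between replicates, which that test takes into account. With any 1 library left out the counts ranged from 3502 to 6551 for 6 weeks and from 3028 to 5812 for 20 weeks against normal skin, from 4 to 550 for 20 against 6 weeks, from 3 to 5216 for treated against fibrotic skin and from 904 to 3098 for treated against normal skin. The sets ranged from -0.79 to -0.31 and from 0.36 to 0.74.

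Among named genes the only reversals were of genes that had not passed. Under the rescaling they were Cpt1a at 6 weeks against normal skin (-0.046), Thy1 (-0.048) and Mmp2 (-0.15) at 20 weeks against normal skin, Adipoq at 20 against 6 weeks (0.0093) and Cd36 in treated against normal skin (-0.033, and -0.0023 with a pseudocount of 0.1). With 1 library left out the values that changed sign ranged, for 20 weeks against normal skin, over -0.39 to 0.42 for Fn1, -0.0080 to 0.88 for Col3a1 and -0.018 to 0.45 for Mmp2. For 20 against 6 weeks they ranged over -0.37 to 0.25 for Adipoq, -0.064 to 0.33 for Cav1 and -0.59 to 0.036 for Col1a1. In treated against fibrotic skin they ranged over -0.28 to 0.53 for Fn1, -0.30 to 0.46 for Col1a1, -0.37 to 0.52 for Col3a1, -0.23 to 0.24 for Mmp2 and -0.11 to 0.11 for Pfkfb3. In treated against normal skin they ranged over -0.087 to 0.41 for Fn1, -0.51 to 0.74 for Cd36, -0.45 to 0.73 for Adipoq and -0.54 to 0.20 for Cav1. Among the named calls, 57 ended with only the 6 libraries fitted, 27 without the low-value filter, 19 with group weights, 11 with the replicate block, 7 with the pseudocount, 6 with the rescaling, which could not test members of the removed lists, and 1 with the median of ratios; the cause was not tested. At least 1 fit without a library lost the call of 7 of 32 named genes at 6 weeks and 7 of 30 at 20 weeks against normal skin, 1 of 3 for 20 against 6 weeks, 28 of 28 for treated against fibrotic and 19 of 30 for treated against normal skin.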

Other observations

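The tests in this part were chosen only after the result was seen, although the lists were fixed earlier. Of the T and NK cell genes, adjusted over the list alone, 6 of 17 members were higher and 1 lower at 20 than at 6 weeks, while over all genes none passed (adjusted p from 0.0659 to 0.16). These p-values rest on the spread pooled over all 12 libraries, which includes the treated libraries outside this comparison. With only the 6 libraries compared 478 genes were called, but the result of these members in that fit is not given here. Cd8a, the CD8 alpha chain gene of cytotoxic T cells, stood at 7.85 ± 1.12 FPKM at 20 weeks and 0.297 ± 0.214 at 6 weeks (SD, n = 3 each), a log2 difference of 2.78. The cytotoxic granule genes Nkg7 and Gzma differed by 2.24 and 2.42, Cd8b1 by 2.53, the T cell receptor complex genes Cd3g and Cd3e by 1.40 and 1.09, and Cd4 by -0.96. In treated replicates 1, 2 and 3 Cd8a stood at 12.2, 0.680 and 0.185 FPKM, and the interferon-induced chemokine gene Cxcl9 at 147, 7.05 and 5.00.

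Of the cytokine genes 6 of 23 were lower and 1 higher at 20 than at 6 weeks adjusted over the list alone, and this list and the T and NK cell list had an adjusted p = 0.789 with an estimated correlation. The lower ones were Saa3 (-4.66), Il1b (-2.87), Cxcl5 (-2.85), Cxcl2 (-2.50), Cxcl1 (-1.62) and Ccl12 (-1.15), several of them neutrophil attractants, and the higher one was the T cell chemokine gene Ccl5 (2.29). Of the Wnt and hedgehog genes 4 of 21 were lower, Lef1 (-1.88), Nkd2 (-0.92), Wif1 (-0.77) and Wnt5a (-0.56). None of these passed over all genes in the fit that pools the spread of all 12 libraries. The groups overlapped for Saa3, Il1b, Cxcl5, Cxcl2 and Cxcl1, because replicate 3 of 6 weeks stood below replicate 1 of 20 weeks: Saa3 was at 464, 435 and 12.2 FPKM in the 6-week replicates and at 22.5, 2.16 and 1.24 in those of 20 weeks. They also overlapped for Cd3e.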
